A study of Homo sapiens with 14 samples.

How the data were processed

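Gene expression was measured in cultured human endometrial stromal cells, the connective tissue cells of the uterine lining. The cells of all 14 samples had been decidualized for 14 days with E2P4 per the labels (estradiol and progesterone), which turns these cells into the secretory cells that surround an implanting embryo. They were collected without further treatment (0 h, 3 samples), or after 3 h or 12 h in control conditioned medium (CCM, from stromal cells that had not been decidualized, 3 samples at each time) or trophoblast conditioned medium (TCM, 3 samples at 3 h and 2 at 12 h). Groups and times came from the sample labels. The labels do not say whether samples of a group came from separate cultures or donors, so p-values measure only the spread between these samples, which may be technical. Replicate numbers follow the order of deposit, only name a sample and pair nothing.

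Total RNA was extracted with Trizol and labelled with biotin for Affymetrix whole-genome oligonucleotide arrays, per the labels' protocols. The deposited values are intensities, 1 linear signal value for each of 54675 probe sets on each array, and GCOS 1.1 is named per the submitters' processing notes. The handling of background and of the paired mismatch probes is not given in the sources used here, nor is a genome build, and no detection calls were used. The 2% trimmed mean of every array lay between 500.05 and 500.068, so each array had been scaled on its own to one target. The array medians still ranged from 111 to 216.7. The number of arrays limits the precision.

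A platform annotation table named the probe sets. Apart from 62 control probe sets, 41091 had 1 gene symbol, 1801 had several and 11721 had none. Entrez gene identifiers matched 41037 of those with 1 symbol to a RefSeq gene table, and no symbol changed. Probe sets with several symbols or none were used only where every probe set was tested. XIST and Y-linked genes (70 probe sets) were left out of every step.

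The following rules were fixed before the data were examined, and their values were then read from the data. Values under the pooled 20th percentile (a signal of 32.4) were raised to it, and log2 was taken. No further normalization was to follow if the arrays' 2% trimmed means lay within 10% of each other, and quantile normalization otherwise. The trimmed means above met this rule, so none followed. Probe sets in the lowest 40% by mean over all arrays were left out, and each gene was represented by its brightest remaining probe set, which left 14273 genes. On each array 0.378% to 1.67% of these genes were at the floor. A fold is the ratio of geometric means, and where every array of the dimmer group was at the floor it is given as a lower bound.

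Comparisons were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend). All 14 samples in 5 groups shared 1 estimate of the spread, and p-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The comparisons were TCM against CCM at 3 h and at 12 h, CCM against 0 h at each time, and the difference between the TCM effects at 12 h and 3 h. Every adjusted p below comes from limma. The 26 gene lists, fixed in advance from textbook knowledge, were tested with camera, limma's test of a list against all other genes, with a preset correlation of 0.01 between genes and adjustment over the 26 lists. A correlation estimated from the data was the alternative. The test ranks a list against the other genes, so a list's median and the direction of the test can differ in sign. They did so for 7 lists at 3 h and 1 at 12 h in TCM against CCM, none of them past the threshold.

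Named genes were chosen by a rule fixed in advance. For TCM against CCM at each time these were the 12 largest rises and 12 largest falls past the threshold whose arrays did not overlap between the groups, up to 4 of the called members of each list with the largest changes, and PRL, IGFBP1 and FOXO1 whether called or not. For the other comparisons they were up to 5 rises and 5 falls, without the rule on overlap for the difference between times.

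The fit was tested on simulated data with 200 changed genes among the 14273 in each of 20 simulations. For TCM against CCM at 3 h it recovered 9.66%, 59.3% and 86.5% of genes changed by 1, 2 and 3 on the log2 scale, and 4.9% of its calls were false. At 12 h, with 2 TCM samples, it recovered 4.13%, 46.5% and 75.7%, and 5.32% were false. In the simulated comparison of CCM 3 h with 0 h, which held no change, it made 0.05 false calls on average. The list test, run for TCM against CCM at 3 h on simulated independent genes, called a list of 20 genes shifted by 1 in 20 of 20 simulations and 1 of 500 unshifted lists. Genes that vary together were not simulated. Every group was simulated with the same spread. In the data the CCM 3 h arrays were less alike, with mean correlations within the group of 0.784 to 0.848 against at least 0.913 elsewhere. The rates may therefore not hold for comparisons with CCM 3 h.

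The alternatives changed the filter on dim probe sets, the floor, the normalization (quantile), the variance model, array weights, the summary of a gene's probe sets, the samples in the fit and the threshold, or left out each sample in turn. The sample titles carry 2 series of numbers, each holding every group, whose meaning is not stated, and the series was also fitted as a block. After the data had been seen, 2 alternatives were added: the ACTB 3' to 5' ratio as a covariate, and leaving out the 4 arrays on which that ratio was above 2. Genomic positions are not given because no build is named.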

Results

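The response of decidualized stromal cells to soluble signals from the trophoblast, the cell layer through which an embryo invades the uterine lining, was examined on 14 arrays. They comprised 3 untreated 0 h controls, 3 samples each of CCM 3 h, CCM 12 h and TCM 3 h, and 2 samples of TCM 12 h. CCM controls for the change of medium. It may also carry factors of the stromal cells that conditioned it, so a difference between TCM and CCM can come from either medium.

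The arrays differed in RNA quality. The ratio of the 3' to the 5' control probe sets of beta-actin (ACTB), which rises when RNA is degraded, was 17.5 on CCM 3 h replicate 2, 3.63 on CCM 12 h replicate 3, 2.52 on 0 h replicate 2 and 2.49 on TCM 3 h replicate 2. It lay between 1.06 and 1.38 on the other 10 arrays. The group means were 6.55 ± 9.48 for CCM 3 h, 1.68 ± 0.711 for TCM 3 h and 1.57 ± 0.822 for 0 h (SD, n = 3 each). They were 1.95 ± 1.45 for CCM 12 h (SD, n = 3) and 1.35 ± 0.0307 for TCM 12 h (SD, n = 2). No difference in the log2 ratio was detected between the 5 TCM and the 6 CCM arrays (two-sided exact permutation p = 0.656). Between TCM and CCM the two-sided exact permutation p was 1 at 3 h and at 12 h, where the arrays allow no p below 0.1 (20 splits at 3 h, 10 at 12 h). The mean correlation with the other arrays of its group was 0.784 for CCM 3 h replicate 2, 0.820 and 0.848 for the other CCM 3 h arrays and at least 0.913 for every array of the other groups.

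**Figure D1:**
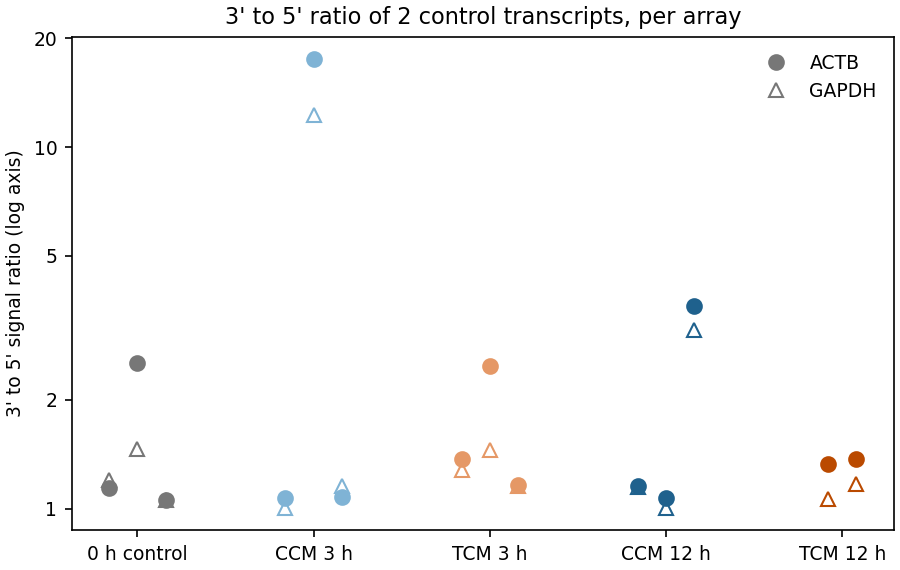
Ratio of 3' to 5' signal (log axis) of the ACTB (filled circles) and GAPDH (open triangles) control probe sets, 1 point per array, by group. CCM 3 h replicate 2 stands at 17.5 for ACTB and 12.25 for GAPDH, and the 2 TCM 12 h arrays at 1.33 and 1.37 for ACTB.

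TCM against CCM at 3 h asked which transcripts differ early between the 2 media. Genes of inflammatory and interferon signalling were higher in TCM. CXCL10, an interferon-induced chemokine, was 60.6-fold higher, at 14.00 ± 0.998 against 8.08 ± 0.14 on the log2 scale (SD, n = 3 each; adjusted p = 1.71e-05). IL6, a cytokine of the acute phase response, was 42.2-fold higher, at 14.41 ± 0.63 against 9.01 ± 0.97 (adjusted p = 1.39e-04). Apart from these, DEPP1, a target of FOXO transcription factors, was 38.9-fold higher, at 13.84 ± 0.10 against 8.56 ± 0.32 (adjusted p = 1.55e-06). It stood at 12.91 ± 0.22 at 0 h, so this fold comes largely from a lower level in CCM, and TCM was not tested against 0 h. In all, 84 of 14273 genes passed the threshold, 71 higher and 13 lower, every one by at least 2-fold. These p-values use the spread of all 5 groups, while the CCM 3 h arrays were less alike than those of the other groups. The shared spread may therefore be too small for this comparison. With only the groups compared, which also leaves fewer samples to estimate the spread, 21 genes passed.

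Other large rises at 3 h were the interferon-induced IFI44L (at least 22.8-fold, with every CCM array at the floor) and IFIT2 (15.7-fold, with 1 of 3 CCM arrays at the floor), the neutrophil chemokine CXCL2 (21.4-fold), and PTX3, a secreted pattern recognition protein (20.2-fold). They also included the metalloreductase STEAP4 (20.6-fold), the integrin subunit ITGB8 (19.6-fold), the kinase MAP3K8 (19.3-fold), the amino acid transporter SLC7A2 (17.9-fold) and the protease inhibitor SERPINA3 (17.3-fold). Their adjusted p ranged from 6.37e-05 (SERPINA3) to 0.0477 (ITGB8). On the 3 CCM arrays PTX3 stood at 9.99, 9.92 and 7.03 and CXCL2 at 11.38, 8.54 and 8.48 (log2). The low array raises the fold of PTX3, and the high one lowers that of CXCL2. A second probe set of CXCL2 was lower in TCM, with a log2 change of -0.85. The second probe sets of STEAP4 and IFIT2 stood at 2.27 and 2.16, not called. The 2 other probe sets of ITGB8 had changes of 0.69 and 1.03. On the probe set used, 1 of 3 CCM arrays was at the floor, and the group means of ITGB8 were 9.89 at 0 h, 7.25 in CCM and 11.54 in TCM. ID1 and ID3, inhibitors of basic helix-loop-helix factors and targets of BMP signalling, were 22.7-fold (adjusted p = 0.00624) and 11.6-fold (adjusted p = 0.0216) lower. The CCM arrays were widely spread, at 11.16 ± 1.60 for ID1 and 9.66 ± 1.23 for ID3 (log2, SD, n = 3 each). RASD1 was 9.32-fold, the pseudogene FAM86C1P 7.87-fold (1 of 3 TCM arrays at the floor), CARD10 7.84-fold, SLC60A1 6.63-fold, ZNF503 5.36-fold and the homeobox gene DLX5 4.60-fold lower. NUAK1 was 4.17-fold, CBARP 4.06-fold, the ovarian and uterine transcription factor FOXL2 3.30-fold and C8orf58 2.82-fold lower (another probe set at -0.51).

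By gene list, 12 of the 32 interferon-stimulated genes measured rose at 3 h and none fell, or 25 when adjusted over the list alone. The list's median change was 1.86 (camera adjusted p = 8.72e-32, and adjusted p = 0.0497 with an estimated correlation). CMPK2 (15.6-fold) and RSAD2 (13.1-fold) were among them. Of 22 NF-kB targets and feedback genes 7 rose, or 13 adjusted over the list alone, with a median change of 1.60 (adjusted p = 3.25e-18, and adjusted p = 0.0188 with an estimated correlation). TNFAIP6 (9.14-fold), NFKBIZ (7.17-fold) and NAMPT (5.87-fold, with its call lost with the number series as a block, adjusted p = 0.0531) were examples. Among 14 cytokines IL6 alone passed over all genes and 8 rose when adjusted over the list alone, with a median change of 1.86 (adjusted p = 2.28e-10, and adjusted p = 0.0188 with an estimated correlation). Of 17 chemokines 3 rose, CXCL10, CXCL2 and CXCL11 (at least 14.9-fold, with every CCM array at the floor), or 6 adjusted over the list alone. Their median change was 1.21 (adjusted p = 4.99e-08), and the call was lost with an estimated correlation (adjusted p = 0.066).

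Immediate early genes, with ZFP36 (3.79-fold) and KLF6 (2.89-fold) higher among 29, the prostaglandin pathway, with the prostaglandin E synthase PTGES (2.82-fold) higher among 15, and HLA class I antigen presentation, with none of 16 genes called, also passed as lists. Adjusted over the list alone, 5, 4 and 0 of their members rose and none fell. Their median changes were 0.07, 0.15 and 0.11, with adjusted p of 0.0303, 0.0196 and 0.0465. These calls were lost with an estimated correlation (adjusted p = 0.526, 0.0668 and 0.499), and each was lost without CCM 3 h replicate 1 (adjusted p = 0.0599, 0.174 and 0.705) and without TCM 3 h replicate 1 (adjusted p = 0.166, 0.0509 and 0.208). Immediate early genes were also lost without CCM 3 h replicate 2, the array of highest 3' to 5' ratio (adjusted p = 0.23), without TCM 3 h replicate 3 (adjusted p = 0.0698) and under quantile normalization (adjusted p = 0.15). They were also lost with array weights (adjusted p = 0.175) and without the 4 arrays of high 3' to 5' ratio (adjusted p = 0.0797). HLA class I genes were lost without CCM 3 h replicate 3 (adjusted p = 0.107), without TCM 3 h replicate 2 (adjusted p = 0.0729) and under quantile normalization (adjusted p = 0.0796). With the lowest 60% of probe sets left out, HLA class I genes (adjusted p = 0.112) and the prostaglandin pathway (adjusted p = 0.0798) were lost. Single members of 4 lists that did not pass were called, BMP2 (3.41-fold higher, a decidual morphogen in the decidualization and TGF-beta lists), HGF (10.1-fold higher, angiogenic factors, with 1 of 3 CCM arrays at the floor and its 3 other probe sets between 0.20 and 1.38), SERPINA3 (protease inhibitors) and ID1 and ID3 (TGF-beta, BMP and activin signalling). PRL and IGFBP1, the secreted proteins that mark decidual cells, were not called, with differences of 0.23 ± 0.40 and 0.06 ± 0.42 (log2 ± SE, adjusted p = 0.849 and 0.97). The difference for FOXO1, a regulator of decidualization, was -0.74 ± 0.32 (adjusted p = 0.473), with its other probe set at -1.72, not called. The second probe sets of BMP2 and PTGES stood at 0.89 and 0.66, not called.

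The arrays of the 2 groups did not overlap for any of the 84 genes. Over all genes 10.2% did not overlap, where chance gives 10%. With the number series of the sample titles as a block 101 genes were called, and the median size of the 84 within the 2 series was 2.30 and 2.22, against 2.27 over all arrays. The genes were picked on these same arrays, so the similar sizes of the 2 series are no separate support. The count rested on single arrays. It was 325 without CCM 3 h replicate 1, 46 without replicate 2 and 30 without replicate 3 of that group. The median size of the 84 genes was then 2.64, 2.23 and 2.21. Control probe sets for 18S ribosomal RNA stood at 35190 and 22050 on CCM 3 h replicates 2 and 3, against 114 on replicate 1. The count of 325 thus rests on the 2 CCM arrays of high 18S signal, and no fit of TCM against CCM left out both. The count was 21 and 28 without TCM 3 h replicates 1 and 2. In place of 7 lists, 4 passed without CCM 3 h replicate 1 or TCM 3 h replicate 1. Without the 4 arrays of high 3' to 5' ratio 8 genes passed, all higher, and the median size of the 84 genes was 2.20 against 2.27.

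TCM against CCM at 12 h asked the same of the later response. CSF3, the granulocyte growth factor, was at least 218.5-fold higher, at 12.79 ± 1.37 (SD, n = 2) with all 3 CCM arrays at the floor (adjusted p = 0.00153). The chemokine CXCL1 was 123-fold higher, at 15.47 ± 0.15 (SD, n = 2) against 8.53 ± 1.60 (SD, n = 3; adjusted p = 0.00353). CXCL6 was 97.5-fold, CXCL5 70.6-fold, CXCL3 67.4-fold, IL6 67.3-fold and CXCL2 52.1-fold higher. For CXCL5 and CXCL3 1 of 3 CCM arrays was at the floor, and a second probe set of CXCL2 had a change of 1.09. The monocyte chemokines CCL8 and CCL2 were 66.6-fold and 46.2-fold higher. In all, 152 genes passed, 97 higher and 55 lower, each by at least 2-fold.

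Other large rises at 12 h were the interferon-induced RSAD2 (72.6-fold, adjusted p = 1.71e-04) and CMPK2 (40.8-fold), and COXFA4L3, a mitochondrial protein gene (87.8-fold). Large falls were LONRF2 (25.8-fold, adjusted p = 0.00109), ID3 (21.1-fold), the kinesin KIF26B (20.9-fold), the smooth muscle protein calponin CNN1 (13.6-fold) and the histone methyltransferase EHMT2 (11.3-fold). Both other probe sets of EHMT2 were higher, with changes of 0.80 and 1.32. LONRF2, KIF26B, KLF4, SYTL5 and PSAT1 each had a second probe set, not called, with a smaller log2 change (-1.99 for LONRF2, -1.77 for KIF26B, -1.42 for KLF4 and -1.29 for PSAT1). For CNN1, EHMT2 and PCDH10 1 of 2 TCM arrays was at the floor. Then came the retinoic acid binding protein CRABP2 (8.56-fold), the transcription factor KLF4 (8.46-fold), the intermediate filament nestin NES (7.95-fold), LMO7 (7.59-fold, with another probe set at 0.18), SYTL5 (7.44-fold), the protocadherin PCDH10 (7.40-fold) and the serine synthesis enzyme PSAT1 (7.39-fold).

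All 17 chemokines had positive changes at 12 h, 9 of them past the threshold and 13 when adjusted over the list alone. The list's median change was 4.04 (adjusted p = 2.37e-25, and adjusted p = 0.00539 with an estimated correlation). Of 14 cytokines 4 rose, CSF3, IL6, IL24 (20.7-fold) and IL1B (18.6-fold), or 6 over the list alone, with a median of 2.18 (adjusted p = 1.01e-11, and adjusted p = 0.0075 with an estimated correlation). Of 22 NF-kB genes 8 rose, or 17 over the list alone, with a median of 2.01 (adjusted p = 4.29e-24, and adjusted p = 0.00735 with an estimated correlation). They included the complement component C3 (28.2-fold), PTX3 (a change of 4.70 on the log2 scale), the adhesion molecule ICAM1 (12.1-fold) and NAMPT (10.1-fold). Of 32 interferon-stimulated genes 12 rose, or 27 over the list alone, with a median of 2.13 (adjusted p = 2.42e-34, and adjusted p = 0.0298 with an estimated correlation). MX1 (10.1-fold) and OAS2 (7.29-fold) followed RSAD2 and CMPK2.

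Among the 16 HLA class I genes none passed over all genes, 4 rose when adjusted over the list alone, and all 16 changes were positive with a median of 0.95 (adjusted p = 1.02e-08, and adjusted p = 0.0317 with an estimated correlation). In the prostaglandin pathway (15 genes) PTGES was 19.9-fold higher (adjusted p = 1.95e-05) and the prostaglandin E receptor PTGER2 was 3.37-fold lower. Over the list alone 3 rose and 2 fell, with a median change of 0.76 (adjusted p = 0.00459, and adjusted p = 0.0354 with an estimated correlation). Of 21 matrix proteases the interstitial collagenase MMP1 (15.1-fold) and the stromelysin MMP3 (3.02-fold) rose (list adjusted p = 0.00397, but adjusted p = 0.108 with an estimated correlation). The 7 metallothioneins all had positive changes, with a median of 1.77 and 3 past the threshold over the list alone (adjusted p = 1.62e-05, but adjusted p = 0.195 with an estimated correlation). Cholesterol synthesis (18 genes) and the hypoxia response (26 genes), none with a called member, also passed as higher, with medians of 0.49 and 0.24 (adjusted p = 0.027 and 0.0122). With an estimated correlation these became adjusted p = 0.602 and 0.0604. Cholesterol synthesis was lost without TCM 12 h replicate 1 (adjusted p = 0.769), CCM 12 h replicate 1 (adjusted p = 0.22) or CCM 12 h replicate 3 (adjusted p = 0.317). Hypoxia was lost without TCM 12 h replicate 1 (adjusted p = 0.156) and under quantile normalization (adjusted p = 0.0538), and the prostaglandin pathway without TCM 12 h replicate 2 (adjusted p = 0.0605) and with the lowest 60% of probe sets left out (adjusted p = 0.0716). Cholesterol synthesis was also lost without the filter on dim probe sets (adjusted p = 0.0561) and without the 4 arrays of high 3' to 5' ratio (adjusted p = 0.371).

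Cell cycle genes (26, with MCM6 3.62-fold lower) and extracellular matrix genes (32, none called) passed as lower at 12 h, with medians of -0.53 and -0.39 (adjusted p = 0.00459 and 0.00864) and with 4 and 1 members lower when adjusted over the list alone. Neither held with an estimated correlation (adjusted p = 0.424 and 0.233). Cell cycle genes were lost without CCM 12 h replicate 2 (adjusted p = 0.357) or TCM 12 h replicate 2 (adjusted p = 0.46), and extracellular matrix genes without TCM 12 h replicate 1 (adjusted p = 0.0535) or the 4 arrays of high 3' to 5' ratio (adjusted p = 0.0566). Called members of lists that did not pass were TGFBI (4.47-fold lower) beside ID3, FZD2 (3.93-fold lower, a WNT receptor), ANGPT1 (7.06-fold lower, angiogenic factors), ASNS (4.90-fold lower) beside PSAT1 among ATF4 targets, KLF4 among immediate early genes, and SERPINA3 (24.1-fold higher). Among smooth muscle and pericyte markers, ACTA2 was 3.05-fold lower beside CNN1, with a second ACTA2 probe set at 0.12. The second probe sets of ANGPT1 and FZD2 stood at -1.49 and -0.84, not called. PRL, IGFBP1 and FOXO1 were not called, with differences of 0.09 ± 0.45, 0.27 ± 0.47 and -0.75 ± 0.36 (log2 ± SE, adjusted p = 0.98, 0.93 and 0.476).

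Of the lists called at 1 time, immediate early genes stood at adjusted p = 0.199 at 12 h. At 3 h matrix proteases stood at 0.137, metallothioneins at 0.0956, cholesterol synthesis and hypoxia at 0.726 each, cell cycle at 0.426 and extracellular matrix at 0.362. Lists that did not pass at either time are given by their camera adjusted p at 3 h and then at 12 h. Decidualization markers stood at 0.19 and 0.712, the insulin-like growth factor axis at 0.19 and 0.84, angiogenic factors at 0.309 and 0.835 and protease inhibitors at 0.137 and 0.551. TGF-beta, BMP and activin signalling stood at 0.188 and 0.0579, WNT signalling at 0.483 and 0.137, ATF4 and the unfolded protein response at 0.931 and 0.0558 and the NRF2 response at 0.407 and 0.912. Markers of other cell types gave 0.941 and 0.241 for trophoblast, 0.692 and 0.712 for leukocytes, 0.877 and 0.389 for endothelium, 0.457 and 0.652 for epithelium and 0.202 and 0.0687 for smooth muscle and pericytes.

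For none of the 152 genes did the arrays of the 2 groups overlap. Over all genes 32.1% did not, where chance gives 20% for 3 arrays against 2. With the number series as a block 201 genes were called, and the median size of the 152 within the 2 series was 2.40 and 2.31, against 2.50 over all arrays. These genes too were picked on the same arrays, so the similar sizes are no separate support. The count was 36 and 64 without TCM 12 h replicates 1 and 2, 70 without CCM 12 h replicate 1 and 259 without CCM 3 h replicate 2, which enters only through the shared spread. It was 158 without the 4 arrays of high 3' to 5' ratio.

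**Figure D2:**
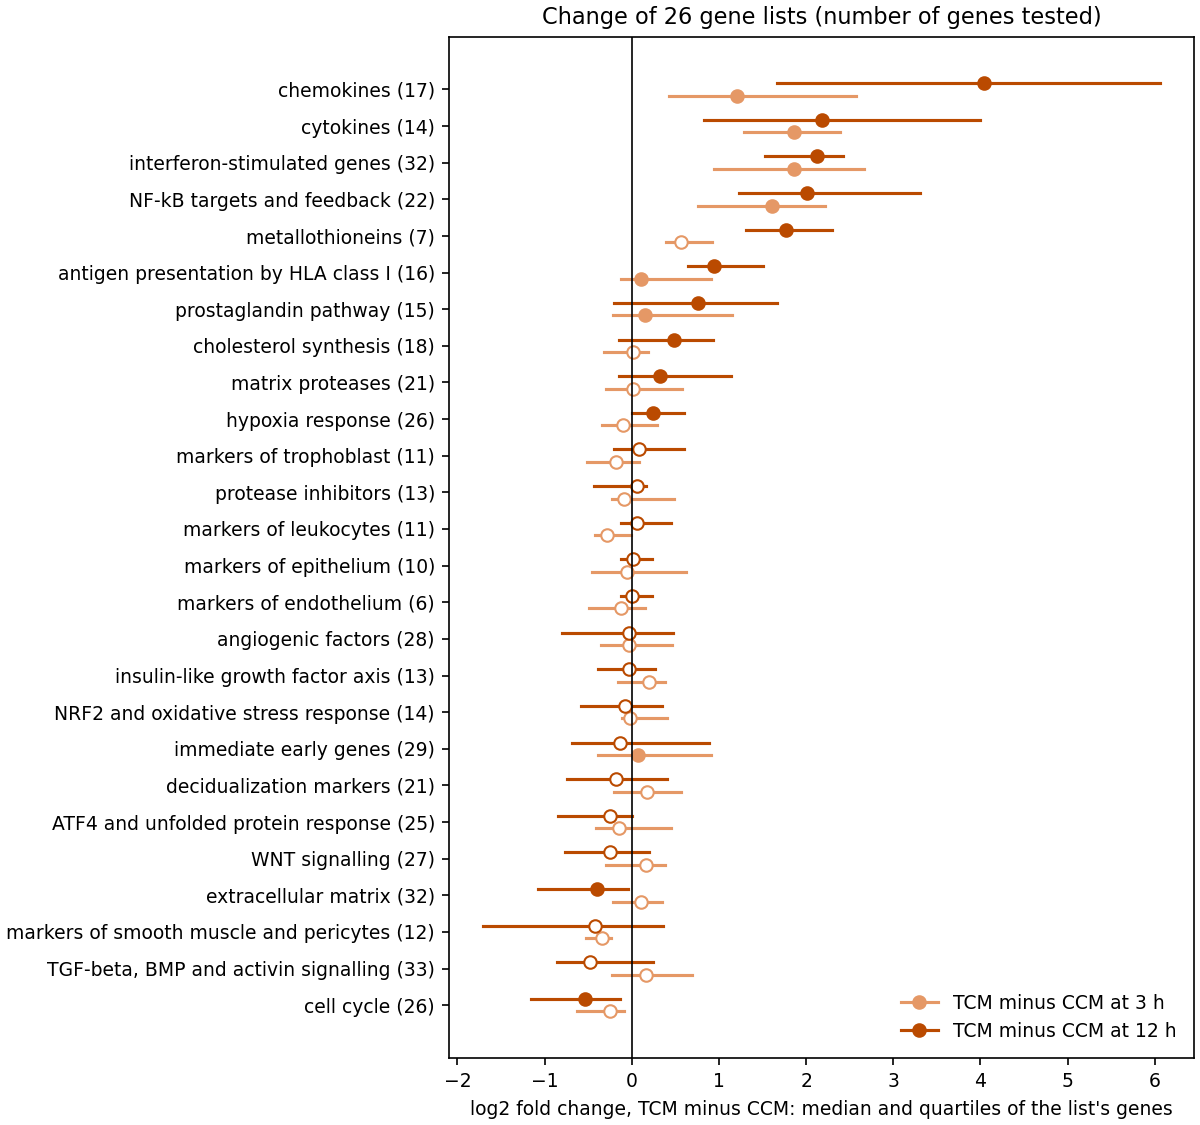
Median (circle) and quartiles (line) of the log2 fold change of TCM over CCM for the genes of each of the 26 lists, at 3 h (light) and 12 h (dark), with the number of genes tested in parentheses. Filled circles mark lists past the threshold in the test with a preset correlation; the chemokine median is 1.21 at 3 h and 4.04 at 12 h.

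**Figure D3:**
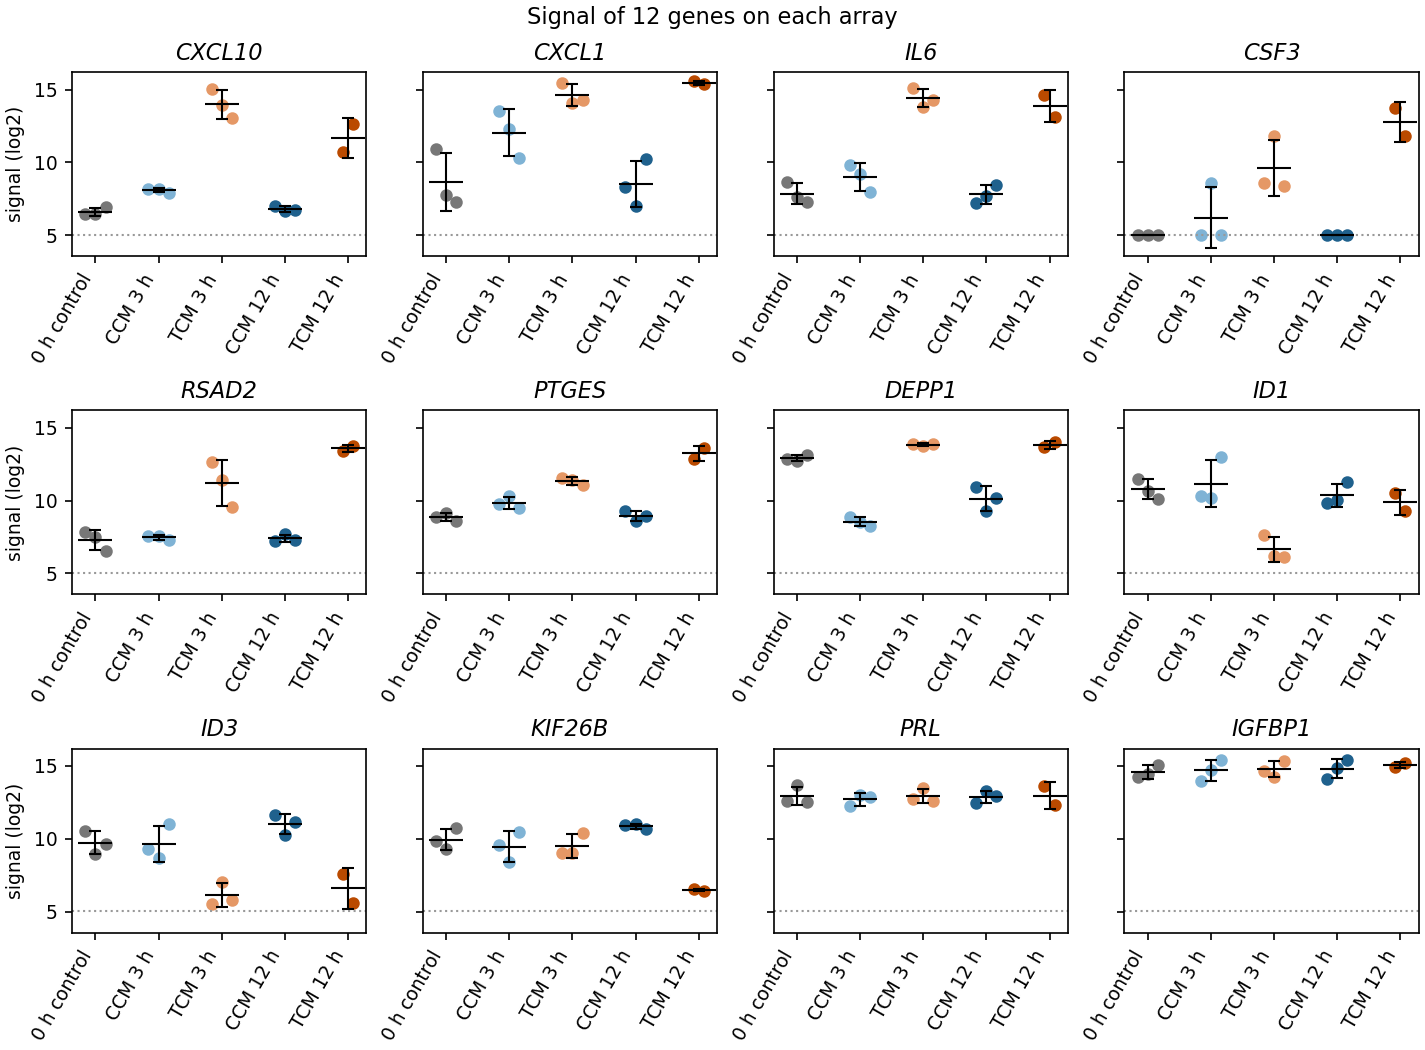
Log2 signal of 12 genes on every array (points), with the group mean and SD (black bars, n = 2 for TCM 12 h and 3 otherwise) and the floor (dotted line). CXCL10, IL6 and DEPP1 are high in both TCM groups, ID3 is low in both, and PRL and IGFBP1 overlap between TCM and CCM at each time.

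Of the genes higher in TCM, 31 were called at both 3 h and 12 h, where lists drawn independently would share 0.483. Of the genes lower in TCM, 4 were shared, against 0.0501. Descriptively, with genes not independent, Fisher's exact test (one-sided) gave p = 3.13e-50 and p = 1.37e-07. The 2 comparisons share no sample, but both use the spread estimated from all arrays. Their calls need not be independent, so the numbers drawn independently may be too low a baseline. No gene was called in opposite directions. Of the 84 genes called at 3 h, 79 had the same sign at 12 h, and of the 152 called at 12 h, 126 had the same sign at 3 h, against 54.7% of all genes. Shared higher calls numbered 47 and 17 without CCM 3 h replicates 1 and 3, 14 and 17 without TCM 3 h replicates 1 and 2, and 15 and 17 without TCM 12 h replicates 1 and 2. Shared lower calls numbered 0 without TCM 12 h replicate 2, 2 without TCM 3 h replicate 2, and 1 without CCM 3 h replicate 3, CCM 12 h replicate 1, CCM 12 h replicate 3, TCM 3 h replicate 1 or TCM 12 h replicate 1.

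The difference between the TCM effects at 12 h and 3 h, tested directly, passed for 6 genes. ADORA2B, the low-affinity adenosine receptor, stood at -0.25 (TCM minus CCM, log2) at 3 h, where it was not called, and rose by 3.42 at 12 h (difference 3.67 ± 0.53 SE, adjusted p = 0.0315). PTGES rose 2.82-fold at 3 h and 19.9-fold at 12 h (difference 2.82 ± 0.45 SE, adjusted p = 0.0459). TMEM200A, FIBIN and the decoy receptor TNFRSF10D had values of 0.44, 0.25 and 0.81 at 3 h, not called, and fell at 12 h, with changes of -2.50, -2.61 and -2.40 (adjusted p of the difference 0.0315, 0.0459 and 0.0459). The call of TNFRSF10D was lost with the number series as a block (adjusted p = 0.0504), and its second probe set had a difference of -1.41, not called. The antiviral zinc finger gene ZC3HAV1 rose by 1.56 at 3 h and stood at -1.44 at 12 h, not called (adjusted p of the difference 0.0459). Its 2 other probe sets had differences of -3.21 and -0.43, not called. As lists, chemokines and HLA class I genes were higher and TGF-beta and extracellular matrix genes lower at 12 h than at 3 h (median differences 2.12, 0.68, -0.75 and -0.43, adjusted p = 1.12e-06, 0.00911, 0.0092 and 0.00911). None held with an estimated correlation (adjusted p = 0.346 for chemokines and 0.363 for each of the others). HLA class I genes were lost without CCM 3 h replicate 2 (adjusted p = 0.0536) or TCM 3 h replicate 3 (adjusted p = 0.116), TGF-beta genes without CCM 3 h replicate 2 (adjusted p = 0.071) and under quantile normalization (adjusted p = 0.0512), and extracellular matrix genes without CCM 3 h replicate 1 (adjusted p = 0.223). With array weights TGF-beta genes (adjusted p = 0.103) and extracellular matrix genes (adjusted p = 0.121) were lost, and without the 4 arrays of high 3' to 5' ratio HLA class I genes (adjusted p = 0.0613) and TGF-beta genes (adjusted p = 0.137). The list count was 8 without CCM 3 h replicate 3 and 10 without TCM 3 h replicate 1. The 6 gene calls did not hold under quantile normalization, where 0 genes passed, and between 0 and 2 passed when any 1 array was left out.

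**Figure D4:**
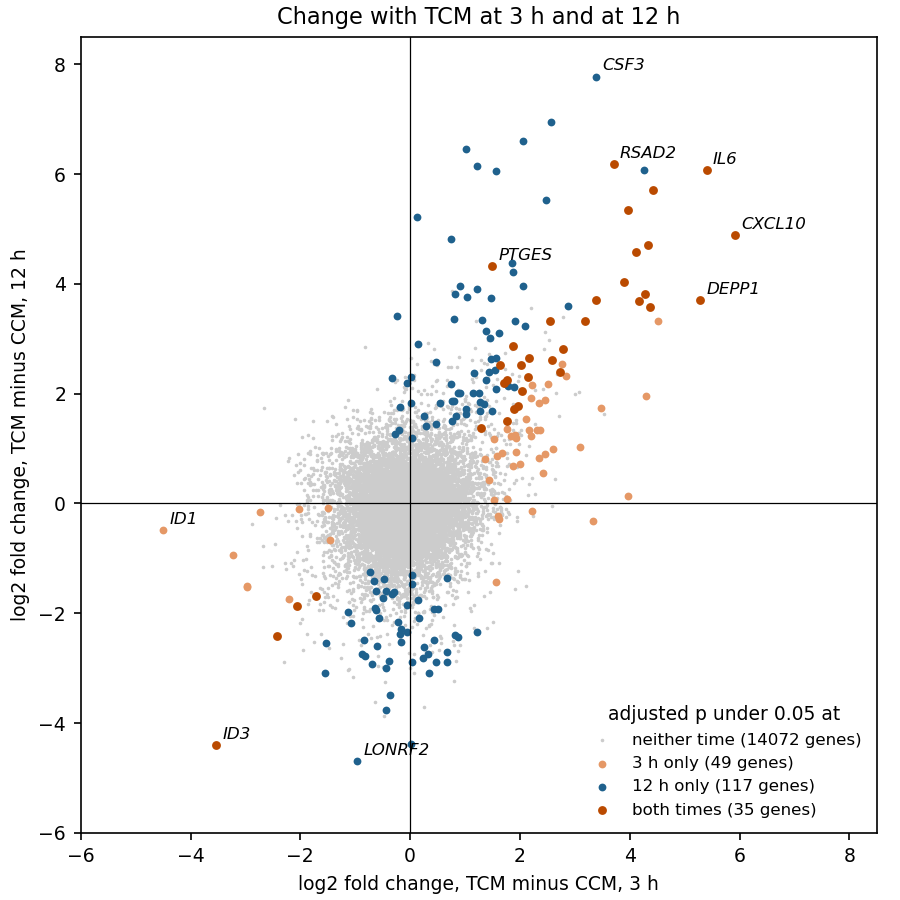
Log2 fold change of TCM over CCM for each of the 14273 genes at 3 h (horizontal) and 12 h (vertical), coloured by the time at which the adjusted p was under 0.05. The 35 genes called at both times lie at the upper right (higher) and lower left (lower), 49 were called at 3 h and not at 12 h and 117 at 12 h and not at 3 h.

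CCM against 0 h asked for the effect of the control medium and of the time in it, and at 3 h it holds the array with an ACTB 3' to 5' ratio of 17.5. The signal of the 18S ribosomal RNA control probe sets was 35190 and 22050 on CCM 3 h replicates 2 and 3. It was 114 on CCM 3 h replicate 1 and between 68.0 and 1511 on all other arrays. TCM against CCM at 3 h holds these CCM arrays too. At 3 h DEPP1 was 20.4-fold lower than at 0 h, at 8.56 ± 0.32 against 12.91 ± 0.22 (SD, n = 3 each; adjusted p = 2.47e-05). The cyclin gene CCNG2 was 5.06-fold lower (adjusted p = 0.0491), with 1 of its 4 other probe sets higher at 0.35. The stress response factor ATF3 was 5.34-fold higher (adjusted p = 0.0326), with 1 of its 2 other probe sets at -0.09, and the NF-kB target TNFAIP2 was 4.66-fold higher (adjusted p = 0.0491). No other gene passed, and 1244 had an unadjusted p under 0.05. Chemokines, NF-kB targets and immediate early genes were higher as lists (medians 1.08, 0.97 and 0.65, adjusted p = 9.35e-07, 7.34e-10 and 0.00325), with 8, 9 and 9 members higher when adjusted over the list alone and 2 immediate early genes lower. TGF-beta and WNT signalling were lower (medians -0.31 and -0.29, adjusted p = 0.0453 each). No list held with an estimated correlation (adjusted p = 0.131, 0.131, 0.511, 0.522 and 0.131 in that order). Immediate early genes were lost without CCM 3 h replicate 1 (adjusted p = 0.305) or 0 h replicate 3 (adjusted p = 0.22). TGF-beta genes were lost without CCM 3 h replicate 2 (adjusted p = 0.593), 0 h replicate 1 (adjusted p = 0.178), CCM 12 h replicate 3 (adjusted p = 0.0521) or TCM 3 h replicate 1 (adjusted p = 0.0517), and under quantile normalization (adjusted p = 0.198). WNT genes were lost without CCM 3 h replicate 1 (adjusted p = 0.228), CCM 3 h replicate 3 (adjusted p = 0.102), 0 h replicate 1 (adjusted p = 0.0679) or 0 h replicate 3 (adjusted p = 0.0802), and under quantile normalization (adjusted p = 0.0533). With the lowest 60% of probe sets left out both TGF-beta (adjusted p = 0.142) and WNT genes (adjusted p = 0.187) were lost. TGF-beta genes were also lost with array weights (adjusted p = 0.279), with the ACTB ratio as a covariate (adjusted p = 0.156) and without the 4 arrays of high 3' to 5' ratio (adjusted p = 0.621). The list count was 3 without CCM 3 h replicate 1 and 8 without CCM 3 h replicate 3.

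At 12 h in CCM, DEPP1 was 6.86-fold lower than at 0 h, at 10.13 ± 0.85 (adjusted p = 0.00984), and no other gene passed, with 330 genes at an unadjusted p under 0.05. Cell cycle, ATF4 and unfolded protein response, hypoxia and extracellular matrix genes were higher as lists (medians 0.60, 0.53, 0.35 and 0.38, adjusted p = 8.47e-06, 1.28e-07, 0.00198 and 0.00502). None held with an estimated correlation (adjusted p = 0.339, 0.0734, 0.0734 and 0.339). Cell cycle genes were lost without CCM 12 h replicate 2 (adjusted p = 0.191), and extracellular matrix genes without 0 h replicate 2 (adjusted p = 0.0906) or CCM 12 h replicate 3 (adjusted p = 0.0762), under quantile normalization (adjusted p = 0.0862) and without the 4 arrays of high 3' to 5' ratio (adjusted p = 0.469). The list count was 10 and 8 without 0 h replicates 1 and 2. DEPP1 stayed past the threshold at 3 h under every alternative run. The 3 h count was 34 without CCM 3 h replicate 1 and 7 without CCM 12 h replicate 3. It was 2 without 0 h replicate 2, CCM 12 h replicate 2 or TCM 3 h replicate 1, and 1 without 0 h replicate 3, CCM 3 h replicates 2 or 3, TCM 3 h replicates 2 or 3 or either TCM 12 h array. The 12 h count was 0 without 0 h replicate 1, 0 h replicate 3 or CCM 12 h replicate 3.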

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

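The tests on scaling, trophoblast RNA and leukocytes were chosen after the result they measure had been seen.

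The TCM effect differed between 12 h and 3 h, by the interaction test, for ADORA2B (3.67), PTGES (2.82), FIBIN (-2.87), TMEM200A (-2.93), ZC3HAV1 (-2.99) and TNFRSF10D (-3.21), all on the log2 scale. No group held enough samples for a test of single outlying samples.

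The control probe sets for 18S ribosomal RNA were 42.1-fold above the mean of the 0 h controls on CCM 3 h replicate 2 and 26.4-fold above it on CCM 3 h replicate 3. Among probe sets without a single gene symbol, 8 were called for TCM against CCM at 3 h (6 higher) and 16 at 12 h (10 higher).

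The comparison that gave 84 genes between TCM and CCM at 3 h holds CCM 3 h replicate 2, the array with the highest 3' to 5' ratio. If degraded RNA there had made the whole pattern, the genes would not move at 12 h, a comparison without any 3 h array. With CCM 12 h replicate 3 also left out, their median change at 12 h in the 3 h direction was 1.58 (quartiles 0.86 and 2.65). Of the 84 genes 75 had the same sign, against 50.4% of all genes. These values cannot show how many single calls at 3 h, or how much of their size, rest on CCM 3 h replicate 2. Without that array 39 of the 84 genes were still called at 3 h, and the median size of the 84 was 2.23. After quantile normalization the median absolute change of the 84 genes was 2.28 (quartiles 1.83 and 3.17), against 2.27 without it. The size thus did not depend on the choice between these normalizations. It cannot decide on scaling of each array to one target, since quantile normalization also sets every array to one distribution. The genes had also been picked for large changes, the smallest 1.28, where the median over all genes was -0.12.

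For TCM against CCM at 3 h, the 10 splits of the 6 arrays are too few for a share under 0.05: the real split gave 84 genes, 1 split of the 10 gave as many, and the highest other gave 0. For the lists at 3 h, 3 of the 10 splits gave as many as the real 7, the highest other giving 8. The number of lists therefore did not set the real grouping apart from other splits. This concerns the number of lists and not any single list.

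Where the chemokine, cytokine, NF-kB and interferon lists rose at 12 h, trophoblast markers, dim ones included, had a median change of 0.0268 (quartiles -0.33 and 0.47), and 0 of 20 were called, with changes from -1.18 (CYP19A1) to 1.19 (TFAP2C). The smallest median of the 4 lists was 2.01 (NF-kB), so trophoblast RNA carried over with the medium is argued against as the whole cause, but a small share stays open, since several markers are near the floor, HLA-G, PAPPA and TFAP2C were already bright in CCM (13.75, 13.74 and 11.16) and 2 of the markers are also in other lists. Leukocyte markers had a median change of 0.0591 (quartiles -0.09 and 0.48), and 0 of 23 were called, with changes from -2.10 (CD53) to 1.09 (LCP1, at 12.39 in TCM and 11.30 in CCM) and with TYROBP at 0.90 and GZMB at 0.87, so leukocytes are argued against as the whole cause and a small share stays open. Without CCM 12 h replicate 3, the most degraded array of this comparison, the smallest median of the 4 lists was 2.06 and all 4 stayed past the threshold with a preset correlation (with an estimated one, interferon genes had an adjusted p of 0.067). A response of the stromal cells to a factor in the medium remains a hypothesis, consistent with these tests, and differences between the media other than trophoblast factors were not tested.

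For CCM against 0 h, 10 splits are again too few for a share under 0.05. At 3 h the real split gave 4 genes, 1 split of the 10 gave as many, and the highest other gave 0. It gave 5 lists, 4 of the 10 splits gave as many, and the highest other gave 9. At 12 h it gave 1 gene, 2 of the 10 splits gave as many, and the highest other gave 2. It gave 4 lists, 9 of the 10 splits gave as many, and the highest other gave 7. The number of lists at either time, and of genes at 12 h, therefore did not set the real grouping apart from other splits.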

How the results depend on the processing

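Of these alternatives, the ACTB ratio as a covariate and leaving out the 4 arrays were chosen after the data had been seen. Direction was kept for each called gene named in the text and each list called. For genes whose arrays do not overlap between groups, leaving arrays out could not have turned it. The filters on dim probe sets, the variance model, the threshold and the fit of only the groups compared leave a gene's change as it is. They could not have turned it either. Other probe sets of CXCL2 at 3 h and of EHMT2, LMO7 and ACTA2 at 12 h did go the other way. The chemokine, cytokine, NF-kB and interferon lists passed under all 24 settings at both times, except chemokines at 3 h with an estimated correlation (adjusted p = 0.066). Counts moved with the setting, and the cause was not tested. No paired analysis was run, since no label states which samples belong together. Only the 2 number series, each with every group, were matched, as a block. A finer grouping by the order of the numbers would have been a guess and was not fitted. The number series as a block left the 5 gene counts within 1.5 times, with 80 of the 84 genes at 3 h and 150 of the 152 at 12 h still called. The calls of NAMPT at 3 h (adjusted p = 0.0531) and of TNFRSF10D for the difference between times (adjusted p = 0.0504) were lost. Other settings cost more calls among the genes of largest change and the called list members. Of 46 such genes at 3 h, 40 were lost without the 4 arrays of high 3' to 5' ratio and 33 without the filter on dim probe sets. Without TCM 3 h replicate 1 33 were lost, with only the groups compared 29, and with array weights 0. Of 57 at 12 h, 27 were lost without the filter, 24 without CCM 12 h replicate 1 and 0 with array weights. Signal over background limits dim genes, for which no detection calls were used.

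TCM against CCM at 3 h (84 genes) gave 26 without the filter on dim probe sets, 46 without the variance trend, 242 with array weights, 21 with only the groups compared and 8 without the 4 arrays of high 3' to 5' ratio. At 12 h (152) it gave 92 without the filter, 92 without the trend, 705 with array weights (314 higher, 391 lower), 275 with only the groups compared and 312 with the ACTB ratio as a covariate.

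CCM 3 h against 0 h (4) gave 1 without the filter, without the trend, with mean probe sets, with only the groups compared, with the ACTB ratio and without the 4 arrays, 2 with 60% of probe sets left out, without a floor and with every probe set tested, and 8 with array weights. CCM 12 h against 0 h (1) gave 0 without the filter, without the trend, with only the groups compared and without the 4 arrays, and 4 with array weights. The difference between times (6) gave 1 without the filter, 3 with mean probe sets, 30 with array weights, and 0 under quantile normalization, without the trend, with every probe set, with only the groups compared and without the 4 arrays.

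With an estimated correlation, lists called went from 7 to 3 and from 12 to 6 for TCM against CCM at 3 h and 12 h, and from 5, 4 and 4 to 0 for CCM at 3 h, CCM at 12 h and the difference between times. CCM 3 h gave 3 lists with 60% of probe sets left out and under quantile normalization. CCM 12 h gave 7 with the number series as a block and without the 4 arrays. The difference between times gave 8 lists with 60% left out and 2 with array weights.

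Leaving out 1 sample at a time gave 21 to 325 genes for TCM at 3 h, 36 to 259 at 12 h, 1 to 34 for CCM 3 h, 0 to 1 for CCM 12 h and 0 to 2 for the difference. Lists called ranged from 4 to 9, 10 to 13, 3 to 8, 4 to 10 and 3 to 10 in that order, and shared calls from 14 to 47 higher (31) and 0 to 5 lower (4). A lone TCM 12 h sample was assumed to vary like the other groups.

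Signs turned for PRL and IGFBP1, which were never called. At 3 h PRL was -0.011 without CCM 3 h replicate 1 and -0.040 without TCM 3 h replicate 2 (highest with 1 sample left out 0.391), and IGFBP1 was -0.35 with array weights, -0.31 without CCM 3 h replicate 1 and -0.24 without TCM 3 h replicate 3 (highest 0.405). At 12 h PRL was -0.045 under quantile normalization, -0.13 without CCM 12 h replicate 1 and -0.56 without TCM 12 h replicate 1 (highest 0.734), and IGFBP1 was -0.081 without CCM 12 h replicate 1 (highest 0.576).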

Other observations

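DEPP1 and CCNG2, the 2 genes lower in CCM 3 h than at 0 h, are both known targets of FOXO transcription factors. DEPP1 stood at 12.91 ± 0.22 at 0 h, 8.56 ± 0.32 in CCM 3 h and 10.13 ± 0.85 in CCM 12 h, but at 13.84 ± 0.10 in TCM 3 h (SD, n = 3 each) and 13.83 ± 0.25 in TCM 12 h (SD, n = 2). CCNG2 stood at 12.28 ± 0.37 at 0 h, 9.94 ± 0.71 in CCM 3 h, 11.68 ± 0.53 in CCM 12 h and 11.48 ± 0.34 in TCM 3 h (SD, n = 3 each), and at 11.69 ± 0.28 in TCM 12 h (SD, n = 2). Unlike DEPP1, its means in CCM and TCM were alike at 12 h.

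A hypothesis that FOXO targets fall together in CCM, written down before its test but after these 2 genes had been seen, was tested on 23 other measured FOXO targets, of which 19 were lower in CCM 3 h than at 0 h and none was called on its own, with a median change of -0.69 (camera adjusted p = 2.39e-08 over 2 lists, and adjusted p = 6.03e-04 with an estimated correlation). Further tests were chosen after this result had been seen, since CCM 3 h replicates 2 and 3 both carry a high 18S signal. The median was -0.59 without replicate 2 (camera adjusted p = 3.73e-09) and -0.75 without replicate 3 (adjusted p = 9.41e-08). Over all arrays it was -0.32 at 12 h in CCM (adjusted p = 0.0013). All of these use the same 0 h arrays, so a high level on those arrays would give the same sign at both times. The 12 h value is therefore no separate support. A loss of FOXO activity in CCM may be a candidate explanation, found and tested on the same arrays. TCM against CCM adds nothing to this, since it uses the same CCM arrays and an opposite sign is expected from shared noise (median 0.26, adjusted p = 0.00408 at 3 h and median 0.0061, adjusted p = 0.997 at 12 h), and the list was not tested in TCM against 0 h. In 1 of the 10 splits of the 6 arrays, the real one, the unadjusted p was as small as 1.20e-08, and the smallest of the others was 0.00218, but 10 splits are too few for a share under 0.05. Progesterone and glucocorticoid receptor targets, tested for a fall of steroid receptor activity, were lower for 10 of the 20 measured (3 of them also FOXO targets). Their median change was 0.04 (quartiles -0.54 and 0.75, camera adjusted p = 0.965), where CCNG2 fell by 2.34. Without both CCM 3 h replicates 2 and 3 their median was -0.51, with 11 of 20 lower. That of the FOXO targets was -0.61, with 17 of 23 lower. These values rest on a lone CCM 3 h array, so they decide neither.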
